A study of Mus musculus with 6 samples.

How the data were processed

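RNA of 6 samples of sorted tumour-infiltrating regulatory T cells was measured on a NanoString nCounter mouse cancer immune panel. The panel held 750 endogenous and 20 housekeeping probes, with 6 positive and 8 negative controls. Per the labels, tumours were made into single-cell suspensions with DNase and collagenase and cells were sorted by fluorescence before RNA extraction. Per the file headers, the deposited lane files hold the raw molecule count of each probe, with no normalization or background step recorded. The authors also deposited a table of normalized signal values for the 770 gene probes. Set against the counts, each sample's values equalled its counts times 1 factor, to within 0.05 counts for 100% of probes, with counts of 0 placed at 1 count. The factors were 4.56, 5.57 and 2.73 in the knockout and 5.16, 6.67 and 10.3 in the control samples, and their basis was not given in the sources used here. A further 6 lanes of the cartridge were not used here.

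Groups were taken from the genotype in the labels, 3 knockout and 3 control samples, numbered in accession order. Lanes counted 280 of 280 requested fields, except 279 in control replicate 1. Negative controls averaged 5.5 to 7 counts per lane, a background that would make up 5.83% to 9.08% of the total gene counts, and 17.3% in control replicate 3. A probe was tested if it exceeded the mean + 2 SD of the negative controls of its lane in at least 3 of 6 lanes, a rule blind to group, which left 371 probes. Because background does not scale with RNA, normalized counts of probes near background run higher in shallow lanes.

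Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors over the tested probes, estimateDisp, glmQLFit and glmQLFTest, two-sided), with group as the only term and Benjamini-Hochberg adjustment over all tested probes. The common biological coefficient of variation was 0.152. Standard errors were derived from the log2 fold change and the quasi-likelihood F. Normalized counts are counts divided by the effective lane size and multiplied by its mean over lanes. Gene lists with at least 3 tested probes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated per list, and with fry. Camera compares a list with the other tested genes of an immune panel. An exact permutation test of 3 against 3 samples cannot go below p = 0.1, so none is given.

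The design, the 34 lists, of which 10 hold markers of other cells, the filter, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Kdr and Foxp3, each gene past the threshold, the 2 members of each tested list with the smallest unadjusted p, and Il2ra, Ctla4, Ikzf2, Il10, Tgfb1, Pdcd1, Ifng, Cd4 and Cd8a where they passed the filter. Of the genes this rule named, 1 is not reported here. List entries were first matched to the panel by exact name. After the first list results had been seen, 2 further entries were matched through letter case or the reference symbol. This added H2-Dma to the tested MHC class II genes, whose camera adjusted p moved from 0.211 to 0.514. The same 5 lists were called with either matching. Accessions of 746 of the 770 probes matched the RefSeq gene table of GRCm38.p6, with 737 symbols equal and 9 different, and 24 did not match. Panel names were kept, and no coordinates are given because the files name no genome build.

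The fit was tested on simulated data drawn from the real means and lane sizes, in 20 simulations with 388 probes tested on average. Of the changed probes that passed the filter, the fit recovered 46.1% at 1.5-fold, 85.2% at 2-fold and 100% at 4-fold. Of its calls, 4% were false. In 20 simulations without change it made 1 gene call and 0 list calls. Probes were drawn independently and background was scaled with lane size. The simulations therefore test neither the preset correlation of the list test nor a background that stays constant over lanes.

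Replicates were compared before averaging. Control replicates 2 and 3 were closer than other pairs of a group, with a biological coefficient of variation of 3.50% against 9.49% or more. A chi-square test over the tested probes found a difference beyond counting noise (p = 0.00123), which lanes of 1 RNA could also show. They were kept as separate samples because the series design calls them biological replicates, and the fit with their counts summed was added. The alternatives were other scaling factors, other filters, background subtraction, leaving out each sample, DESeq2 1.42.0, limma-voom, and limma on log2(value + 1) of housekeeping-normalized counts or of the deposited signal values. Lanes thinned to 26665 counts in 20 draws, control replicates 2 and 3 summed, and TMM factors over all 770 probes were added after the data were examined.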

Results

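In tumour-infiltrating regulatory T cells, 20 of 371 tested genes had lower and 2 had higher transcript counts in the Kdr knockout than in the control samples (n = 3 each). The largest falls among them were in Klrg1, an inhibitory lectin-like receptor of differentiated effector lymphocytes, and Gzmb, the granule protease granzyme B. Ccr2, a chemokine receptor, and Cd80, a ligand of CD28 and CTLA-4, also fell. Tcf7, a transcription factor of naive and memory T cells, and Slamf6, a receptor of the SLAM family, rose. Foxp3, the transcription factor that defines the lineage, was not called as changed.

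The cells came from SB1 tumours grown in the flank of C57BL/6 mice and were sorted by the yellow fluorescent protein that the Foxp3 allele carries together with Cre recombinase. In 3 samples the mice had floxed Kdr alleles and in 3 samples wild-type Kdr. Kdr encodes VEGFR2, a receptor for vascular endothelial growth factor. The series design calls the samples of each group 3 biological replicates. RNA was counted on a NanoString mouse panel of 770 gene probes, in which colour-coded reporters are counted one molecule at a time without amplification. Total gene counts were 62533, 59265 and 92455 in the knockout samples and 63410, 46626 and 26665 in the control samples. The comparison asks how loss of Kdr in Foxp3-expressing cells alters immune gene expression in these cells.

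Kdr itself gave 2, 1 and 3 counts in the knockout samples and 3, 9 and 3 in the control samples. Each value lay below the background threshold of its own lane, which ran from 11.2 to 16.3 counts. The probe therefore did not check the deletion at this depth, and its position relative to the floxed part was not given in the sources used here. Foxp3 gave normalized counts of 658 ± 43.1 (SD, n = 3) in the knockout and 799 ± 81.8 (SD, n = 3) in the control samples. Its log2 fold change was -0.28 with a standard error of 0.13 and an edgeR quasi-likelihood adjusted p of 0.268.

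Of 371 probes above background and tested, 22 passed a Benjamini-Hochberg adjusted p of 0.05 in the edgeR quasi-likelihood test, 20 lower and 2 higher in the knockout. At an unadjusted p of 0.05 the counts were 46 lower and 22 higher. The median log2 fold change over the tested probes was -0.002. Groups did not overlap for any of the 22 called genes, but these were chosen by p from the same samples, so this is not separate evidence. Groups also did not overlap for 90 of the 371 probes (24.3%), where chance gives 10% if lanes are exchangeable. Lanes differed in depth and background share, and probes of a lane are not independent. The 2 shares therefore do not decide whether more probes changed than were called.

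Gzmb averaged 37.5 ± 4.92 normalized counts in the knockout and 152 ± 6.59 in the control samples (SD, n = 3 each). It was 4.09-fold lower, with a log2 fold change of -2.03, a standard error of 0.16 and an edgeR adjusted p of 4.97e-06. Klrg1 averaged 20.8 ± 1.75 against 86.2 ± 30.4 (SD, n = 3 each), a 4.16-fold lower level with an edgeR adjusted p of 0.00045. Ccr2 averaged 98.6 ± 10.6 against 273 ± 50.9 (SD, n = 3 each) and was 2.75-fold lower, with an edgeR adjusted p of 0.000362. Alcam, an adhesion molecule that binds CD6, fell by 1.37 on the log2 scale (standard error 0.24). Tcf7 rose from 137 ± 32.8 in the control to 259 ± 38.4 in the knockout samples (SD, n = 3 each), 1.86-fold, with an edgeR adjusted p of 0.0128. Slamf6 was 1.72-fold higher, with an edgeR adjusted p of 0.0166. It was called in 11 of 20 alternative analyses, and lost the call under housekeeping scaling and in the DESeq2 test, among others. Irf8, an interferon regulatory factor, lay below background in each knockout lane. Its control mean was 2.20-fold above the background threshold of the knockout lanes. That ratio takes no account of sampling error, so it is not a lower limit on the fall. The edgeR confidence interval of the Irf8 log2 fold change ran from -2.23 to -0.79, and the edgeR adjusted p was 0.0128.

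**Figure D1:**
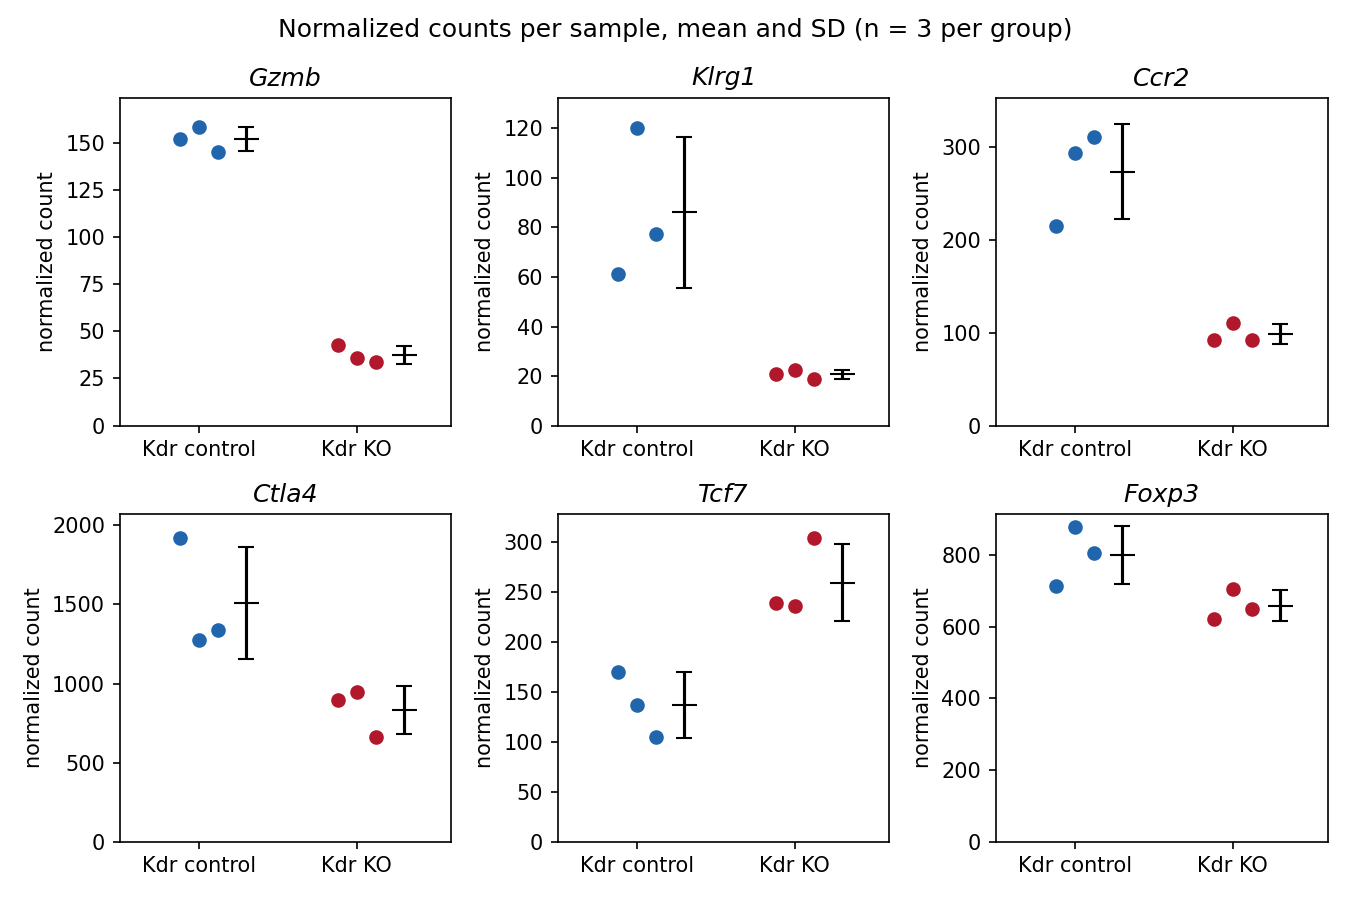
Normalized counts (vertical axis, linear, from 0) of 6 genes in each sample, with control samples in blue and knockout samples in red. Horizontal marks are group means and bars are SD (n = 3 per group). Gzmb averaged 37.5 in the knockout and 152 in the control samples, and Tcf7 259 and 137.

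The receptors that fell included Il7r, the receptor subunit for interleukin 7 (log2 -0.96, standard error 0.18), and Ifngr1, a chain of the interferon gamma receptor (log2 -0.90, standard error 0.18). Hif1a, a transcription factor of the response to low oxygen, fell by 0.61 on the log2 scale. Mapkapk2, a kinase downstream of p38, fell by 0.72, and Isg20, an interferon-induced exonuclease, fell by 0.76 with an edgeR adjusted p of 0.0481. Mapkapk2 was called in 9 and Isg20 in 6 of the 20 alternative analyses.

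**Figure D2:**
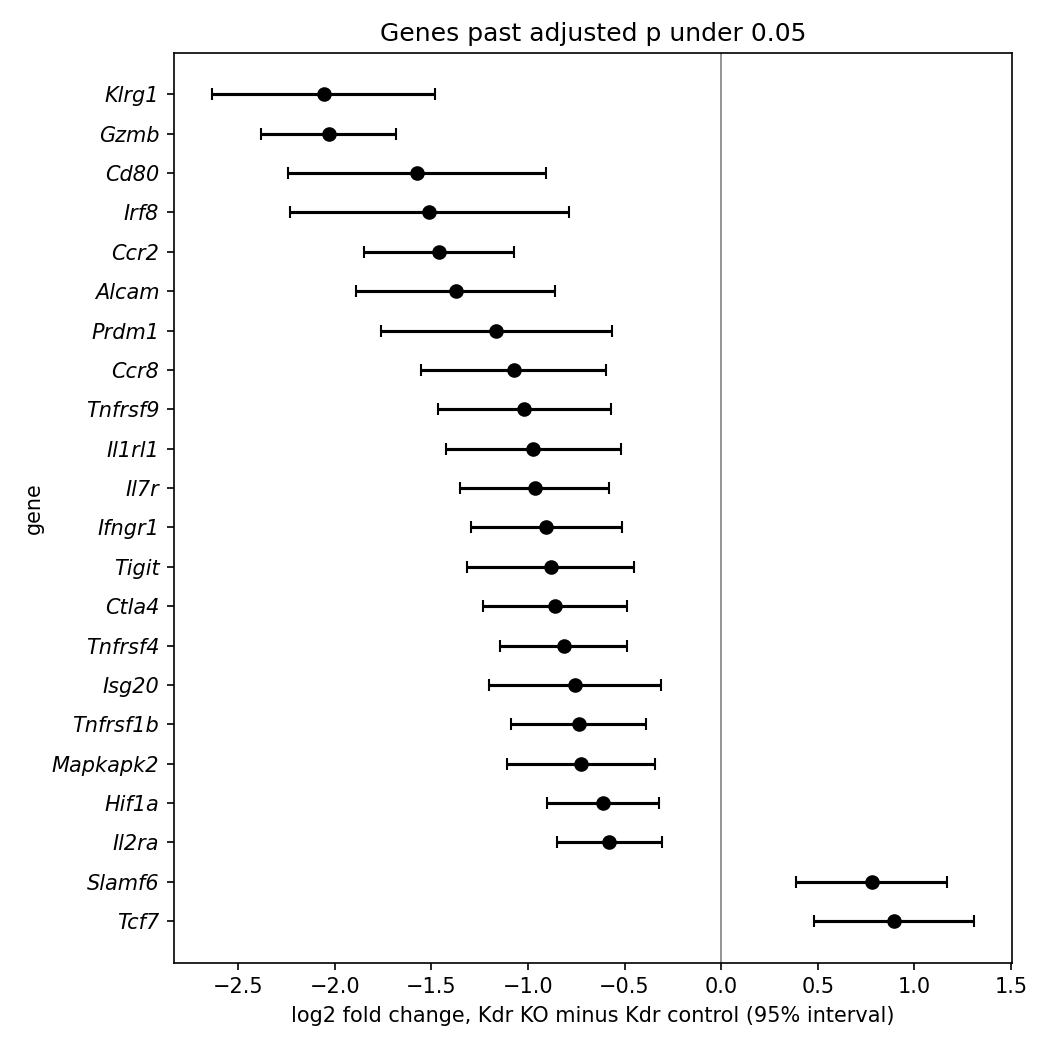
Log2 fold change, knockout minus control (horizontal axis), of the 22 genes past an adjusted p of 0.05 in the edgeR quasi-likelihood test. Points are estimates and bars are 95% intervals. Tcf7 and Slamf6 lie above 0 and the other 20 genes below.

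Of 21 tested genes of effector regulatory T cells in tumours, 8 fell, none rose and 13 did not pass. Adjusted over the list alone, 10 fell. Klrg1, Cd80 (log2 -1.58, standard error 0.31) and Prdm1, which encodes the transcription factor Blimp-1 (log2 -1.16, standard error 0.28), were the members with the lowest estimates. Prdm1 was called in 11 of the 20 alternative analyses. Ccr8 (log2 -1.07), Tnfrsf9, a costimulatory receptor of the tumour necrosis factor family (log2 -1.02), Il1rl1, the receptor for interleukin 33 (log2 -0.97), Tigit, an inhibitory receptor (log2 -0.88), and Tnfrsf1b, a receptor for tumour necrosis factor (log2 -0.74), fell too. The camera test gave the list an adjusted p of 9.73e-06, and an adjusted p of 0.277 with an estimated correlation.

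Among 10 core genes of the lineage, Ctla4, an inhibitory receptor that binds CD80 and CD86, fell by 0.86 on the log2 scale. Tnfrsf4, which encodes the costimulatory receptor OX40, fell by 0.81, and Il2ra, the alpha chain of the interleukin 2 receptor, fell by 0.58. Il2ra was called in 12 of the 20 alternative analyses. The other 7 did not pass, and adjusted over the list alone 4 fell and 1, Nrp1, rose. Ikzf2, which encodes Helios, had a log2 fold change of -0.10, and Nrp1, a co-receptor for VEGF and semaphorins, one of 0.45, neither past the test over all probes. The camera adjusted p of this list was 0.0280, and the adjusted p was 0.277 with an estimated correlation.

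Of 7 suppressive mediators, Gzmb and Ctla4 fell, and the same number fell adjusted over the list alone, while 5 did not pass. Tgfb1 had a log2 fold change of 0.02. The camera adjusted p was 0.00512, and the adjusted p was 0.277 with an estimated correlation. Of 4 cytotoxicity genes, only Gzmb fell over all probes and adjusted over the list alone. Ctsw, a cathepsin of cytotoxic lymphocytes, had a log2 fold change of -0.40. Of the 4 estimates, 2 were below 0, with a median of -0.18. The cytotoxicity list had a camera adjusted p of 0.0195, and an adjusted p of 0.277 with an estimated correlation.

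Of 9 chemokine receptors, Ccr2 and Ccr8 fell, over all probes and adjusted over the list alone, and 7 did not pass. All 9 estimates were below 0, with a median of -0.44, while 8 were with total counts only as the scaling and 6 with TMM factors over all probes. The camera adjusted p was 0.0195, and the adjusted p was 0.277 with an estimated correlation. Some genes stand in more than 1 of these 5 lists, among them 5 of the 21 effector genes, 3 of the 10 core genes and 5 of the 7 suppressive mediators. So do 4 of the 9 chemokine receptors and 1 of the 4 cytotoxicity genes, Gzmb. None of the 5 chemokines tested passed, over all probes or adjusted over the list alone (camera adjusted p 0.232). Ccl5 had a log2 fold change of -1.13 and Ccl3 one of -0.72.

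**Figure D3:**
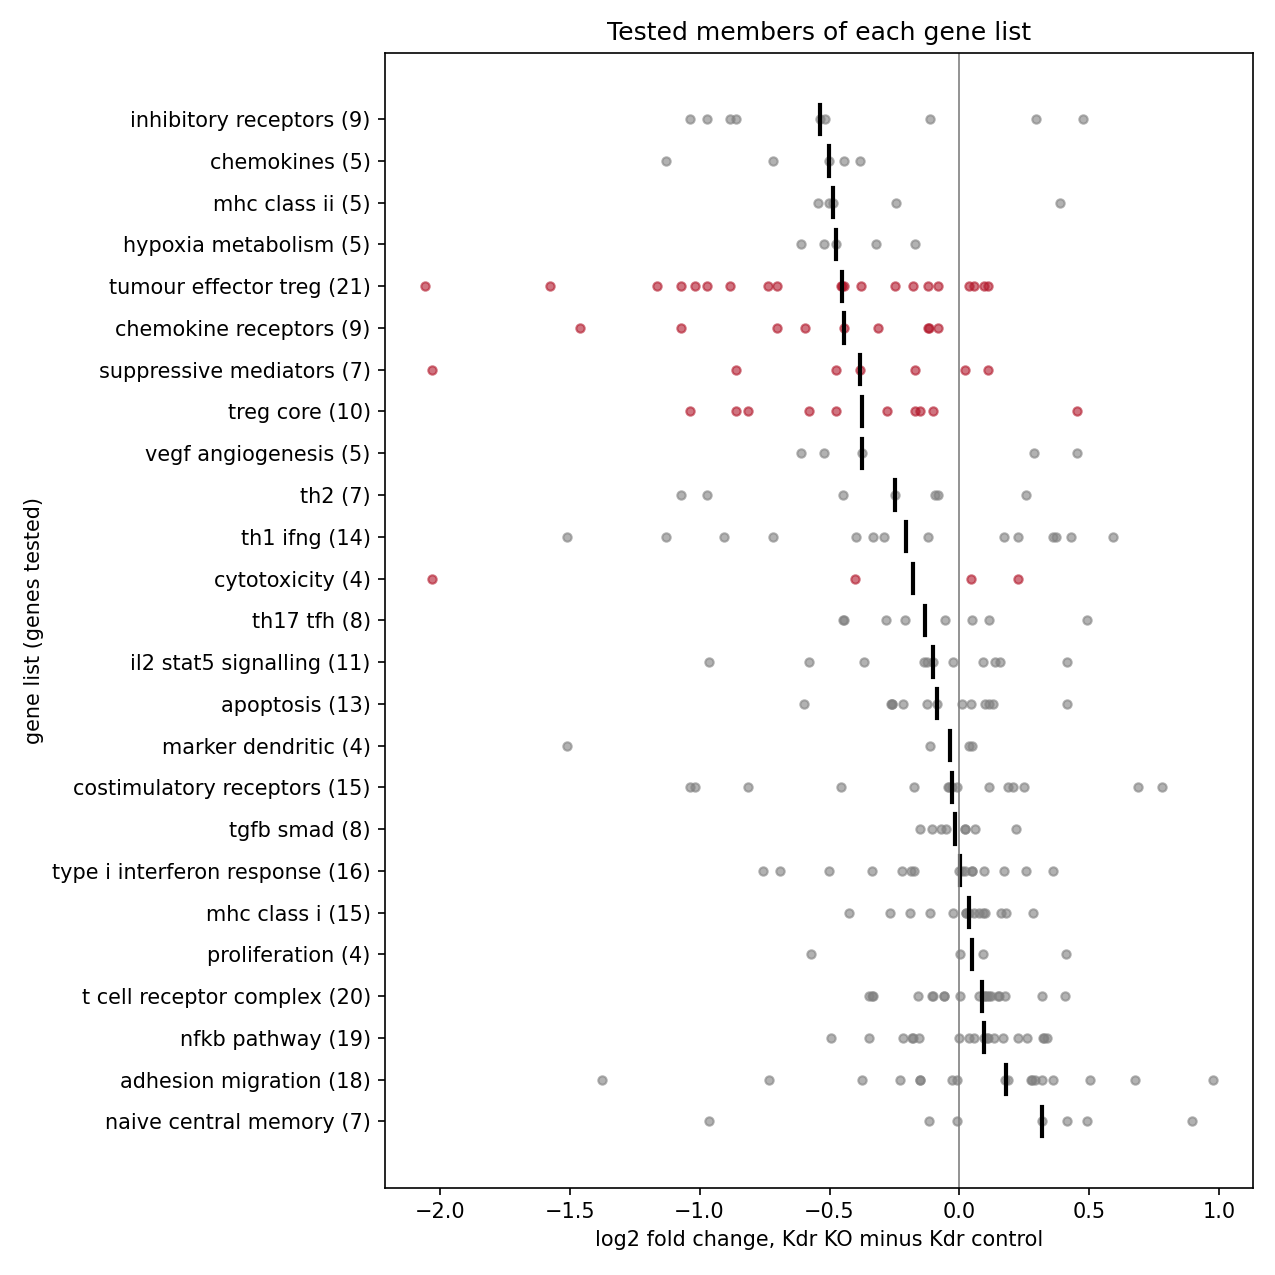
Log2 fold change, knockout minus control (horizontal axis), of the tested members of 25 gene lists (vertical axis, number of genes in parentheses). Points are genes, black marks are list medians, and red points belong to the 5 lists past a camera adjusted p of 0.05 with the preset correlation. The median of the effector list was -0.45.

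The other 20 lists did not pass the camera test. Of 9 inhibitory receptors, Ctla4 and Tigit fell and 3 fell adjusted over the list alone (camera adjusted p 0.130), and Pdcd1, which encodes PD-1, had a log2 fold change of -0.54. Of 15 costimulatory receptors, Tnfrsf4 and Tnfrsf9 fell and Slamf6 rose, with 4 lower and 1 higher adjusted over the list alone (camera adjusted p 0.921). Of 7 genes of naive and central memory cells, Tcf7 rose and Il7r fell, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p 0.232). Il6ra, a chain of the interleukin 6 receptor, had a log2 fold change of 0.49.

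None of 20 genes of the T cell receptor complex passed, over all probes or adjusted over the list alone (camera adjusted p 0.514). Nfatc3 had a log2 fold change of 0.40, Cd6 one of 0.32 and Cd4 one of 0.18. Of 11 genes of interleukin 2 and STAT5 signalling, Il7r and Il2ra fell, as adjusted over the list alone (camera adjusted p 0.541). Of 14 Th1 and interferon gamma genes, Ifngr1 and Irf8 fell, with 3 lower and 1 higher adjusted over the list alone (camera adjusted p 0.803). Of 7 Th2 genes, Ccr8 and Il1rl1 fell, as adjusted over the list alone (camera adjusted p 0.155). None of 8 Th17 and follicular helper genes passed either way (camera adjusted p 0.973), and Maf had a log2 fold change of -0.45. Of 16 type I interferon response genes, Isg20 fell, and adjusted over the list alone Ifi27 fell too (camera adjusted p 0.803).

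No member passed, over all probes or adjusted over the list alone, among 15 genes of MHC class I (camera adjusted p 0.760) and 5 of MHC class II (camera adjusted p 0.514). H2-M3 had a log2 fold change of -0.42, H2-D1 one of -0.19, Cd74 one of -0.50 and H2-Ob one of -0.49. The same held for 4 proliferation genes (camera adjusted p 0.752), 13 apoptosis genes (camera adjusted p 0.973), 19 genes of the NF-kappaB pathway (camera adjusted p 0.450) and 8 of TGF-beta signalling (camera adjusted p 0.879). In these, Myc had a log2 fold change of 0.41, Cdkn1a -0.57, Bcl2 0.41, Ikbke 0.34, Tab1 -0.50, Tgfbr2 0.22 and Itgae -0.15. Of 5 VEGF and angiogenesis genes, Hif1a fell, and adjusted over the list alone Nrp1 rose too (camera adjusted p 0.917). Of 5 hypoxia genes, Hif1a fell, as adjusted over the list alone (camera adjusted p 0.195), and Entpd1, the ectonucleotidase CD39, had a log2 fold change of -0.47. Of 18 adhesion genes, Alcam fell, as adjusted over the list alone (camera adjusted p 0.438), and Itgal, the integrin chain of LFA-1, had a log2 fold change of 0.50. The median, mean and camera direction differed in sign for the type I interferon, proliferation, apoptosis and TGF-beta lists.

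Markers of other cells were mostly below background. None of 7 CD8 T cell, 16 NK cell, 13 neutrophil and 7 melanocyte or epithelial markers was tested, and Il10, Ifng and Cd8a did not pass the filter. Tested markers were Ccr2 and Cd84 of 31 for macrophages and monocytes, Tnfrsf13b of 17 for B cells and Kit of 9 for mast cells. Pecam1 of 12 endothelial and Thy1 of 12 stromal markers were tested too. Of 14 dendritic cell markers 4 were tested, and Irf8 fell, as adjusted over the list alone (camera adjusted p 0.522). Cd1d1, another of them, had a log2 fold change of -0.11.

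The knockout samples were read in lanes 1 to 3 and the control samples in lanes 4 to 6 of 1 cartridge, so lane position and genotype cannot be told apart. The count of called genes was 9 without knockout replicate 3 and 6 on the deposited normalized values, all lower, so that Tcf7 and Slamf6 were not called there. The count was 39 without control replicate 1, with 29 lower and 10 higher. In that fit control replicates 2 and 3, the closest pair, were the only controls.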

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

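The thinned lanes, the summed control replicates 2 and 3 and TMM factors over all probes were chosen after the data were examined. Of the called genes, 21 kept their direction under the 20 alternatives, as did Irf8 under the 16 that tested it, and 6 genes, Alcam, Ccr2, Cd80, Gzmb, Il7r and Klrg1, stayed called under each. Isg20 was called under 6 of the 20, Mapkapk2 under 9, Prdm1 and Slamf6 under 11, Il2ra under 12 and Irf8 under 12 of its 16. After thinning, the median count of called genes was 18, with a range of 9 to 24 over the 20 draws. The count of called genes was 15 without a filter, 17 lower and 4 higher with total counts only, 18 with the DESeq2 test and 23 with limma-voom. It was 18 with TMM over all probes and 20 with control replicates 2 and 3 summed. It was 6, all lower, with limma on the deposited signal values, and the cause was not tested. Leaving out 1 sample gave 9 calls (without knockout replicate 3, all lower) to 39 (without control replicate 1, with 29 lower and 10 higher, Foxp3 among the added genes at a log2 fold change of -0.36). The cause was not tested. The housekeeping scaling moved the median log2 fold change to -0.10 and TMM over all probes, as in the fit without a filter, moved it to 0.14.

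List calls numbered 5, and 0 with an estimated correlation, where 4 lists had an unadjusted p under 0.05. fry called 5, 4 of them shared. Leaving out 1 sample gave 3 list calls (without control replicate 2) to 7 (without knockout replicate 1). Without a filter 7 lists were called, 4 lower and 3 higher (naive and central memory, T cell receptor and NF-kappaB), 3 of them shared. With TMM over all probes 5 were called, 4 of them shared, and the core list was not.

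Among named genes that were not called, 5 changed sign. Tgfb1 gave -0.077 under housekeeping scaling, with the same value by construction when a positive control step came first. It gave -0.014 after background subtraction, -0.013 after thinning, -0.081 with limma on housekeeping-normalized counts, and -0.101 to 0.124 leaving out 1 sample. Without a filter Itgae gave 0.0046, Cd1d1 0.0305 and Ikzf2 0.053, and with TMM over all probes they gave 0.0046, 0.0313 and 0.0532. Leaving out 1 sample, Cd1d1 ran from -0.324 (without control replicate 1) to 0.0058 (without control replicate 3) and Cdkn1a from -0.788 (without control replicate 3) to 0.023 (without control replicate 1). Uncalled Nrp1, Itgal, H2-D1 and Ccl5 became called without control replicate 1, where the close control replicates 2 and 3 were the only controls. Ccl5 was also called without knockout replicate 1 and with TMM over all probes, and Itgal with total counts only. The cause was not tested. No paired analysis was possible because the replicate numbers were given in accession order and only name the samples. Depth was lowest in control replicate 3, with 300 probes above background.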

Other observations

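The tests of other cells, of dilution, of a naive-like state and of total-count and all-probe scaling below were chosen after results bearing on them had been seen. Foxp3, Ikzf2 and Cd4 had log2 fold changes of -0.28, -0.10 and 0.18, none past the test. Ccr7, a homing receptor for lymph nodes, had a log2 fold change of -0.12 and was chosen after its values were seen. Its raw counts, not scaled for lane depth, were 520, 91 and 73 in the control samples.

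Of the 20 genes called lower, 8 belong to the effector list, and an effect of Kdr loss on the 20 is a hypothesis that these tests do not decide. Housekeeping scaling kept 19 of the 20, but it lowers the knockout estimates of all genes, so the test set beforehand could not speak against scaling. Total counts and TMM over all probes raise them. Under both, 14 of the 20 stayed called lower. For these, this argues against a scaling error of the size tried (median log2 fold change 0.10 and 0.14), not against a larger one. Of the 14, Ccr8, Ctla4, Ifngr1, Il1rl1, Irf8, Prdm1, Tigit and Tnfrsf9 lost the call with limma on the deposited signal values. The cause of that loss was not tested. The remaining 6 of the 20, Hif1a, Il2ra, Isg20, Mapkapk2, Tnfrsf1b and Tnfrsf4, lost the call under total counts, TMM over all probes or both. With TMM over all probes their log2 fold changes were -0.43 to -0.67 (standard errors 0.18 to 0.22), against -0.58 to -0.81 (standard errors 0.13 to 0.21) before, so estimates moved toward 0 and errors grew, with none above 0. Unequal depth in total counts is argued against as the whole cause, since a median of 15 stayed called lower over the thinned draws (range 8 to 18). Thinning keeps the background share of each lane, 17.3% in control replicate 3 and 5.83% in knockout replicate 3, so it does not test background. With the negative control mean subtracted, 19 of the 20 stayed called lower.

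Myeloid, NK or CD8 T cells in the control sorts stay open. Of their 54 markers, 2 lay above background in 2 or more control lanes, Ccr2, which fell, and Cd84, at 149 knockout and 126 control normalized counts. Among the highest of those near background, only Eomes was higher in the knockout, with knockout and control means of 12.8 and 8.31. Klrd1 (7.87 and 18.1), Cd244 (3.61 and 11.3), Prf1 (7.12 and 11.8) and Cd68 (8.86 and 14.5) were higher in the control samples. So were Klra6 (3.91 and 11.3) and Itga2 (8.28 and 10.8). Negative controls scaled alike averaged 5.55 and 9.10, so these levels do not decide. Foxp3-negative cells in the knockout sorts would lower each gene by no more than Foxp3. The estimates of 20 of the 20 genes lay below its lower 95% limit, -0.56. Choosing genes by p favours low estimates, so this count was partly set by the choice. Some 95% intervals reached above the limit, as for Il2ra (-0.85 to -0.31) and Hif1a (-0.90 to -0.32), so dilution stays open for such genes. Others lay wholly below it, as for Gzmb (-2.38 to -1.68) and Klrg1 (-2.64 to -1.48).

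Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, gave as many calls, with 22 against 0 for the highest other split, and 10 splits are too few for a share under 0.05. A shift toward a naive-like state may accompany the lower genes, but the naive and central memory list had a camera adjusted p of 0.232, with Tcf7 higher and Il7r lower, so the test left it open. Without a filter this list was called higher, at an adjusted p of 0.0478, and its adjusted p under the other alternatives ran from 0.0691 to 0.591. Lane position followed genotype and cannot be told apart from it.

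Control replicates 2 and 3 differed by a biological coefficient of variation of 3.50%, while control replicate 1 differed from them by 19.6% or more. With replicates 2 and 3 summed into 1 sample, 20 genes were called, all shared with the 22. Whether they share a source was not tested.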
